A study of Mus musculus with 6 samples.

How the data were processed

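RNA sequencing of mouse liver invariant natural killer T (iNKT) cells was re-analysed. The cells were sorted as positive for the CD1d tetramer and for a YFP reporter, and are called iNKT1 cells in the labels. The control group carried a Cre driven from the Tbx21 locus and a Cre-activated YFP in Rosa26. The other group, named cKOHet in the labels, carried in addition 2 floxed Ets1 alleles and 1 floxed Tbx21 allele. Each group had 3 libraries, with the replicate numbers 1, 2 and 4 in the titles. Per the labels' protocols, RNA was isolated with RNeasy mini kits and libraries were made with the Ovation Ultralow system. The design text also names thymic cells and mice with floxed Ets1 alone, which were not analysed here.

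The deposited table holds a signal per Ensembl gene, which the authors describe in its name as normalised HTSeq counts. Per the submitters' processing notes, the tools named were Trimmomatic 0.33, STAR, HTSeq 0.6.1 and DESeq2, with the mm10 build. Their settings, the annotation release, the strand setting and the method of adjustment are not given in the sources used here. The table lists 12942 genes, and the smallest maximum of any gene over the 6 libraries is 5.22, so genes with few reads had been removed before deposit. The columns sum to 5116542, 4996523 and 5205155 in control replicates 1, 2 and 4, and to 5049835, 5088670 and 5219483 in cKOHet replicates 1, 2 and 4. Low values lie in bands 0.938 to 1.048 apart, close to 1 read per unit, but the bands are offset by an amount that differs between libraries, so whole reads were not recovered and the original depth is unknown. Genes with no read in a library are listed at 0 or at a small positive value. The column codes of replicate 1 join 2 names in each group, which the labels do not explain.

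Gene symbols, types and positions were taken from GENCODE M21 on GRCm38 (mm10), which named 12864 of the 12942 identifiers, and 78 kept their identifier. Values were analysed as log2(value + 1). Genes at or above 10 in at least 3 of the 6 libraries were tested, which left 11226. The comparison was cKOHet minus control, with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean-variance trend) and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The design had been planned for normalised counts and was used as planned. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. No edgeR or DESeq2 test was run here, because neither fits values that are not counts. Log2 fold changes are given with their standard errors, levels as mean ± SD of the 3 libraries in a group. The labels describe 3 independent replicates without naming the mice, so p-values measure the spread between these libraries.

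A total of 30 gene lists was fixed before the data were examined: type 1 effector, NK receptor, cytotoxic, cytokine, iNKT2, iNKT17, naive and memory-type, residency, migration, T cell receptor signalling, immediate early, inhibitory receptor, cytokine receptor, cell cycle, apoptosis, Ets family, transcription factor, interferon-stimulated and glycolysis genes, markers of 9 other cell types, and mitochondrially encoded and ribosomal protein genes. Lists with at least 5 tested members (25 of them) were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the 25 lists. Members called over all genes were counted, and counted again when adjusted over the list alone. The named genes followed a rule fixed at the same time: Ets1 and Tbx21; per direction the 10 genes with the largest fold change among called genes with no overlap between groups and a mean of at least 50 in the higher group, leaving out predicted genes, pseudogenes and antigen receptor segments; per list the 4 members with the smallest adjusted p, or 2 where none was called; and 25 lymphocyte genes chosen in advance. Ccr7 and Id3, which are among these 25, did not pass the filter on low values. Any other gene named was chosen after its values were seen, and the text says so.

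The procedure was tested on data simulated for 11082 genes with 200 changed in each of 5 runs. It called 34.3% of genes changed 1.5-fold, 90.1% of those changed 2-fold and 99.7% of those changed 4-fold. Of its calls, 3.5% were false. The simulation used the same dispersion (0.02) for every gene and drew the changed genes from those above a minimum mean. In the real data the spread differed between genes and far more genes were called, so these rates may not hold there. Alternatives covered the pseudocount, the filter, the scaling, the variance model, a replicate block, the threshold and each replicate left out. Added after the data were seen were a correction for GC content and length, a term for the libraries with low Xist, the libraries with high Xist alone, and the left-out replicates without filtering again. Filtering again drops every gene that reaches 10 only in the group that lost a library. A list call that ended with that filter alone may thus reflect the dropped members. TMM factors were computed from the values by a script. Figures and single tests used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genes with near-identical copies, among them Klra, Gbp and ribosomal protein genes, are uncertain, because the handling of reads that match several genes is not given in the sources used here.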

Results

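Transcript levels were measured by RNA sequencing in iNKT1 cells sorted from mouse liver. These are innate-like T cells that recognise lipids on CD1d and depend on the transcription factor T-bet, the product of Tbx21. The control group and the cKOHet group each had 3 libraries, whose normalised read counts summed to between 4996523 and 5219483. The comparison of cKOHet with control libraries asks what the loss of Ets1 together with 1 floxed Tbx21 allele does to these cells, in a series on T-bet and Ets1 deficiency. Levels below are normalised read counts, as mean ± SD with n = 3 libraries per group.

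Ets1, the targeted Ets-family transcription factor (ENSMUSG00000032035, mm10 chromosome 9, 32636221 to 32757820), was far lower in every cKOHet library. Its level was 7391, 6255 and 7787 in the controls and 462, 596 and 441 in cKOHet libraries, a log2 fold change of -3.84 (SE 0.14, limma adjusted p = 1.06e-10), or 14.3-fold. Tbx21 (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331) was at 2568 ± 174 in controls and 2206 ± 98.5 in cKOHet libraries. Its log2 fold change of -0.22 (95% interval -0.46 to 0.02, adjusted p = 0.196) did not pass the threshold, although the groups did not overlap. These are sums over whole genes, so a deleted exon could not be told from the rest of the transcript.

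Of 11226 genes tested, 2407 (21.4%) were called, 1288 higher and 1119 lower in cKOHet libraries. Among them 647 were at least 2-fold higher and 526 at least 2-fold lower. The groups did not overlap at 4015 genes (35.8%, against 10% by chance for 3 against 3 libraries), and 2342 of the calls were among these. The first principal component held 66.9% of the variance and separated the groups. Correlations across genes were 0.964 to 0.969 within groups and 0.878 to 0.899 between them. The design allows 10 splits of the libraries, so no exact permutation test could fall below 0.1.

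The genes that rose most included several that were nearly silent in controls. Calca, which encodes calcitonin and the neuropeptide CGRP, was listed at 0.00 to 1.17 in controls and at 861, 1043 and 620 in cKOHet libraries. Il9r, the interleukin-9 receptor, was at 0.11 to 0.77 in controls and 453, 571 and 325 in cKOHet libraries. Gcg (proglucagon), Tox2 (an HMG-box transcription factor) and Slc6a20a (an amino acid transporter) were listed at 0.00 to 0.11 in controls and averaged 354 ± 106, 338 ± 149 and 192 ± 79.6 in cKOHet libraries. Itgad, an integrin alpha chain, went from 1.96 ± 1.73 to 858 ± 319, and the long noncoding RNA Miat from 2.97 ± 2.48 to 827 ± 81.8. Ccr8, a chemokine receptor, averaged 5.21 ± 4.61 and 419 ± 46.5, and Mmp25, a membrane-bound metalloprotease, 3.15 ± 2.06 and 226 ± 33.6. Itgae, the integrin chain CD103, rose in every cKOHet library but unevenly (161, 1097 and 254, against 6.19 ± 2.53), with a log2 fold change of 5.70 that was 4.89 without cKOHet replicate 2. The fitted values of Itgad, Miat and Ccr8 also moved by over 1.5 times when a control was left out, to 7.75 (from 8.34, without control replicate 4), 7.25 (from 8.02, without control replicate 2) and 5.59 (from 6.58, without control replicate 2), with 7.18 for Ccr8 without control replicate 1, and all stayed called.

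The genes that fell most went nearly silent. Mmp9, a secreted gelatinase, was at 2148, 2665 and 4626 in controls and at 0.01, 0.00 and 6.33 in cKOHet libraries. Cd93, a C-type lectin-like receptor, fell from 578 ± 33.4 to 1.72 ± 2.09, Rflnb, an actin regulator, from 400.5 ± 62.2 to 2.96 ± 2.70, and Plxnd1, a semaphorin receptor, from 442 ± 207 to 4.14 ± 3.77. Hbegf, an EGF-family growth factor, fell from 149 ± 21.3 to 3.32 ± 1.68, and the interferon-induced Ifi44 from 108 ± 57.2 to 1.31 ± 0.64. Igsf23, Ccdc136, Stc2 and Cdc42ep1 averaged 211, 86.6, 81.7 and 66.7 in controls and were listed at 0.00 to 0.08 in cKOHet libraries. The fitted log2 fold changes of Mmp9, Cd93 and Plxnd1 stayed called but moved by 1.5 times or more with single cKOHet libraries, Mmp9 from -10.58 to -11.53 without replicate 4, Cd93 from -8.04 to -8.63 without replicate 1, and Plxnd1 from -6.81 to -5.86 without replicate 2 and to -7.40 without replicate 4.

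**Figure D1:**
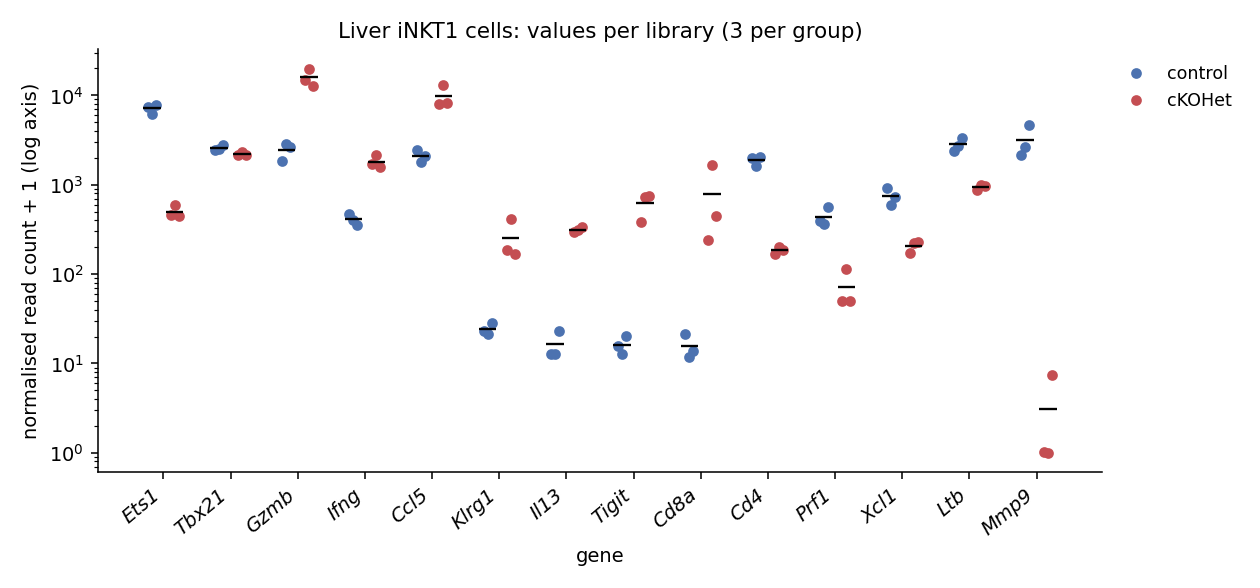
Normalised read count + 1 of 14 genes (log axis) in each library, with 3 control and 3 cKOHet libraries as points and the group means as black bars. Ets1 fell to 441 to 596 in cKOHet libraries, Tbx21 lay at 2127 to 2765 over both groups, and Cd8a was highest in 1 cKOHet library at 1657.

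Effector genes of type 1 lymphocytes moved in both directions, with more rising than falling. Of 23 tested members of the type 1 effector and T-bet-linked list, 10 rose, 4 fell and 9 did not pass (10 higher and 5 lower when adjusted over the list alone). Gzmb, a cytotoxic protease, rose from 2442 ± 525 to 15930 ± 3620 (log2 fold change 2.71, SE 0.18, adjusted p = 5.34e-08). Ifng rose from 408.5 ± 61.5 to 1803 ± 312 and the chemokine gene Ccl5 from 2100 ± 316 to 9750 ± 2900. Il2rb, the receptor chain for interleukins 2 and 15, fell from 20260 ± 338 to 12380 ± 1880 (log2 -0.72), the chemokine receptor gene Cxcr3 from 3432 ± 128 to 2406 ± 170 (-0.51) and the chemokine gene Xcl1 from 749 ± 172 to 206.5 ± 31.4 (-1.84). Hopx was the other member that fell (-1.35, chosen after its values were seen). The T-box gene Eomes was low, at 4.51 ± 7.06 and 17.6 ± 7.50; it was called (log2 2.57, adjusted p = 0.039), but leaving out any library except control replicate 2 ended the call (adjusted p 0.0767 to 0.149 on the same genes). Without control replicate 2 its log2 fold change was 3.67, and without control replicate 4 it was 1.83. The list as a whole was shifted upward (camera adjusted p = 0.0352). With an estimated correlation camera gave an adjusted p = 0.469, although the estimate (0.001) was below the preset 0.01. That version rests on the few residual degrees of freedom of 6 libraries. It called no list in any setting, so its missing call says little about this list. With the filter applied again, the list call also ended without control replicate 2, cKOHet replicate 1 or cKOHet replicate 4 (adjusted p = 0.0525, 0.0937 and 0.102). On the same genes these were 0.0482, 0.054 and 0.0639, so that the call was kept without control replicate 2. It also ended with a filter of 50 (0.0625), library weights (0.0519) and the libraries with high Xist alone (0.0636).

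Cytotoxic genes split. Of 12 tested, 4 rose and 4 fell (5 and 4 when adjusted over the list alone). The list was not called by camera (adjusted p = 0.733) but was called upward by fry (adjusted p = 0.0355). Beside Gzmb, Lamp1, a lysosomal membrane protein, rose from 797 ± 34.3 to 1294 ± 34.9; Gzma and Nkg7 also rose (log2 2.94 and 0.45, chosen after their values were seen), Gzma unevenly (565, 2719 and 411, against 116 ± 39.4). Prf1, which encodes the pore-forming protein perforin, fell from 438 ± 109 to 69.8 ± 36.6 (log2 -2.72, adjusted p = 5.36e-06), and Tnfsf10, the death ligand TRAIL, from 1100 ± 102 to 572.5 ± 79.8. The serpin genes Serpinb6b and Serpinb9 also fell (-0.90 and -0.54, chosen after their values were seen).

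Among 17 secreted cytokines and chemokines, 7 rose and 3 fell (8 and 3 when adjusted over the list alone; camera adjusted p = 0.188). Il13, a type 2 cytokine, rose from 15.3 ± 6.09 to 312 ± 19.5 (log2 4.32, adjusted p = 5.71e-08). Ltb, which encodes lymphotoxin beta, fell from 2831 ± 466 to 941 ± 61.6, and Csf1 fell from 224 ± 183 to 8.62 ± 2.53 (chosen after its values were seen), with Xcl1 as the third.

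Receptors of the NK lineage rose more often than they fell. Of 23 NK cell receptors tested, 11 rose and 4 fell, the same numbers as when adjusted over the list alone. Klrg1, an inhibitory receptor of effector lymphocytes, rose from 23.2 ± 3.88 to 254 ± 134 (log2 3.28), and the Ly49 receptor genes Klra5 and Klra7 rose from 57.6 ± 25.4 to 364 ± 38.0 and from 10.9 ± 4.40 to 88.3 ± 14.4. Klre1 fell from 226 ± 104 to 41.0 ± 19.6, and Klrk1, Klrb1f and Klrc2 also fell (log2 -1.44, -1.78 and -0.86, chosen after their values were seen). Klrb1c, which encodes NK1.1, was not called (1355 ± 1120 and 1106 ± 222, adjusted p = 0.994), with control replicate 4 at 2626, and without that control its log2 fold change was 0.64 (adjusted p = 0.0486 on the same genes). The list was shifted upward (camera adjusted p = 0.044; adjusted p = 0.489 with an estimated correlation). With the filter applied again, the list call ended without control replicate 2 or cKOHet replicate 1, 2 or 4 (adjusted p = 0.167, 0.129, 0.0542 and 0.131). On the same genes these were 0.153, 0.0821, 0.0291 and 0.0841, so that the call was kept without cKOHet replicate 2. It also ended with no filter (0.0725), a filter of 50 (0.0625), library weights (0.0574) and a replicate block (0.0513).

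The coreceptor genes moved apart. Cd4 fell from 1895 ± 236 to 183 ± 17.4 (log2 -3.36, SE 0.14, adjusted p = 3.17e-10). Cd8a was at 20.1, 10.7 and 12.8 in controls and at 237, 1657 and 440 in cKOHet libraries (log2 5.21, adjusted p = 2.19e-06; 4.43 without cKOHet replicate 2 and 5.83 without cKOHet replicate 1). Cd8b1, the other gene of the CD8 T cell marker pair (chosen after its values were seen), was at 17.3 ± 14.0 and 21.4 ± 12.2 and was not called, so that 1 of the 2 tested markers rose, also when adjusted over the list alone. Cd7, an early lymphoid surface protein, was also highest in cKOHet replicate 2 (1220, 4368 and 1308, against 527 ± 76.6; log2 1.87, and 1.27 without that library). Its call (adjusted p = 0.000802) ended with robust eBayes (0.107).

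Genes linked to the other iNKT subsets moved in both directions. Of 11 iNKT2 genes, 7 rose and 2 fell (7 and 3 when adjusted over the list alone; camera adjusted p = 0.103, and 0.0476 without control replicate 1; adjusted p = 0.489 with an estimated correlation, which called no list without that control either). Il17rb, a receptor for interleukin 25, rose from 101 ± 53.2 to 1054 ± 287, and Gata3, the type 2 lineage factor, from 720 ± 51.8 to 1057 ± 92.2 (log2 0.55). Zbtb16, which encodes the iNKT lineage factor PLZF, was called higher (648 ± 21.7 and 954 ± 261, log2 0.53, adjusted p = 0.0267), but on the same genes this ended without control replicate 1, 2 or 4 or cKOHet replicate 4 (adjusted p = 0.0531, 0.0674, 0.0804 and 0.0912). Its log2 fold change hardly moved without these controls (0.55, 0.52 and 0.50) but was 0.31 without cKOHet replicate 4. The folate receptor-like gene Izumo1r fell from 456 ± 115 to 14.8 ± 4.92 and Ccr4 from 210.5 ± 49.8 to 19.2 ± 10.5. Of 10 iNKT17 genes, 6 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.108). Rora and Maf, transcription factors used by several T cell lineages, rose by 1.54 and 1.07 on the log2 scale. Serpinb1a rose from 34.7 ± 19.1 to 327 ± 128 (log2 3.33, or 2.74 without control replicate 2), while Tmem176a and Tmem176b fell (-1.57 and -1.18, the latter chosen after its values were seen).

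Of 48 lymphocyte transcription factors, 14 rose and 8 fell (16 and 10 when adjusted over the list alone; camera adjusted p = 0.199). Ikzf2, which encodes Helios, rose from 232 ± 45.4 to 1013 ± 37.7, and Runx3, a partner of T-bet in type 1 lymphocytes, from 1061 ± 86.0 to 1789 ± 86.3. Klf3 fell from 504 ± 26.7 to 180 ± 19.0. Id2, an inhibitor of E proteins, was at 6975 ± 663 and 6474 ± 750 and was not called. Of 13 other Ets family genes, Erf (84.1 ± 17.5 to 188 ± 38.4) and Etv5 (288 ± 87.4 to 501 ± 35.8) rose and Elk4 (696 ± 42.2 to 530 ± 16.2) fell, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.106). Elk4 lost its call when any library except cKOHet replicate 4 was left out (adjusted p 0.0576 to 0.118 on the same genes). Its log2 fold change moved little in these smaller fits (-0.42 to -0.34, against -0.39 with all 6 libraries). Fli1, a close relative of Ets1, was at 863 ± 12.5 and 1020 ± 93.6 (adjusted p = 0.178).

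Genes of circulation, homing and residency also moved. Of 22 migration receptors and integrins, 10 rose and 4 fell (10 and 5 when adjusted over the list alone; camera adjusted p = 0.0352, and adjusted p = 0.469 with an estimated correlation). Ccr9, a gut-homing receptor, rose from 984 ± 66.6 to 4017 ± 716, and Itgb7, the integrin chain that pairs with CD103, from 3213 ± 232 to 7933 ± 583. S1pr1, the receptor for tissue exit, rose from 57.1 to 78.2 in controls to 195 to 381 in cKOHet libraries, and Klf2, its transcriptional activator, from 45.8 ± 15.1 to 169 ± 41.3. Those that fell included Ccr4, Cxcr3 and Cxcr4 (log2 -1.55 for Cxcr4, chosen after its values were seen). The list call ended without cKOHet replicate 1, 2 or 4 when the filter was applied again, which left 19 members (adjusted p = 0.366, 0.179 and 0.367). On the same genes it was kept without cKOHet replicate 1 or 2 (0.0493 and 0.0177) and ended without replicate 4 (0.0639), as it did with a filter of 50 (0.0625) and in the libraries with high Xist alone (0.0545). Of 14 residency genes, 5 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.33), with Ahr and Prdm1 rising by 1.55 and 1.37 on the log2 scale. Cxcr6, the receptor that holds iNKT cells in liver sinusoids, was at 10390 ± 1260 and 10420 ± 1080, and Itga1 at 545 ± 125 and 711.5 ± 133, neither called. Without control replicate 4, Itga1 was called (log2 0.55, adjusted p = 0.0487 on the same genes). Of 16 naive and memory-type genes, 3 rose (Ccr9, S1pr1 and Klf2) and 4 fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.733, with a median of -0.04 and a mean of 0.15). Lef1 and Foxp1, factors of quiescent T cells, fell by 1.57 and 1.38 on the log2 scale, and Cd27 and Foxo1 also fell (-0.66 and -0.70, chosen after their values were seen). Tcf7 and Il7r were not called (adjusted p = 0.542 and 0.693).

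The list of inhibitory receptors and exhaustion genes included some of the largest increases. Of 14 tested, 6 rose and 1 fell (7 and 2 when adjusted over the list alone). Not all members are inhibitory receptors, and the transcription factor gene Tox2, described above, was among those that rose. Tigit rose from 15.2 ± 3.75 to 625 ± 210 (log2 5.24, adjusted p = 8.36e-09), and Tnfrsf9, the costimulatory receptor 4-1BB, from 152.5 ± 39.4 to 855 ± 163. Cd244a rose unevenly (82.6, 413 and 149, against 21.6 ± 11.3; log2 3.11, and 2.48 without cKOHet replicate 2). The member that fell was Cd101, and Pdcd1, which encodes PD-1, was not called (115 ± 27.3 and 206 ± 139, adjusted p = 0.208; both chosen after their values were seen). The list was shifted upward (camera adjusted p = 0.00699; adjusted p = 0.489 with an estimated correlation), and without cKOHet replicate 2 this ended (adjusted p = 0.244 with the filter applied again, 0.0563 on the same genes).

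Signalling and receptor genes moved in both directions. Of 31 genes of T cell receptor signalling, 5 rose and 6 fell (6 and 6 when adjusted over the list alone; camera adjusted p = 0.765, direction down with a median of 0.02). The phosphatase gene Ptpn6 rose from 1942 ± 337 to 4473 ± 337 and the Ras activator gene Rasgrp1 from 3422 ± 154 to 6299 ± 764, while the kinase gene Fyn fell from 2852 ± 83.3 to 1619 ± 178 and Malt1 from 605 ± 35.5 to 397 ± 41.5. Of 26 cytokine receptors, 5 rose and 6 fell (5 and 9 when adjusted over the list alone; camera adjusted p = 0.28, with a median of -0.18 and a mean of 0.07). Ifngr1, the receptor for interferon gamma, rose from 2543 ± 267 to 9115 ± 1030, and Il1rl1, the interleukin-33 receptor, was at 0.63 ± 0.93 and 61.1 ± 10.8. Il6st and Il12rb1, receptor chains for interleukins 6 and 12, fell from 231 ± 26.0 to 87.0 ± 13.1 and from 982 ± 121 to 557 ± 31.1. Of 21 immediate early and heat shock genes, 5 rose and 3 fell (5 and 6 when adjusted over the list alone; camera adjusted p = 0.733), with Egr1, Nr4a1, Cd69 and Klf6 higher by 1.16, 1.62, 0.87 and 0.87 on the log2 scale.

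Of 25 apoptosis and survival genes, 7 rose and 4 fell (9 and 4 when adjusted over the list alone; camera adjusted p = 0.632, with a median of -0.06 and a mean of 0.33). Genes of the pro-apoptotic BH3-only proteins Bim and Puma were among those that rose, Bcl2l11 from 574 ± 35.1 to 1293 ± 335 and Bbc3 from 17.0 ± 6.38 to 57.7 ± 17.8, as did the cell cycle inhibitor gene Cdkn1a from 10.3 ± 4.38 to 44.0 ± 17.1. Bcl2 was at 2004 ± 35.2 and 1891 ± 173 and was not called. Of 40 cell cycle genes, Nusap1 was called higher (log2 0.84, adjusted p = 0.0263) and Mcm4 lower (-0.44, adjusted p = 0.0202), 0 were called by limma when adjusted over the list alone, and camera gave an adjusted p = 0.733 (direction down with a median of 0.04). Both calls ended without 1 of several libraries, Nusap1 without control replicate 1 or 4 or cKOHet replicate 1 or 4 (adjusted p = 0.117, 0.0907, 0.0635 and 0.111 on the same genes) and Mcm4 without control replicate 2 or cKOHet replicate 1 or 4 (0.108, 0.0707 and 0.0521). In these smaller fits the log2 fold changes were 0.62, 0.76, 0.85 and 0.74 for Nusap1 and -0.35, -0.38 and -0.42 for Mcm4. The direction of the list changed with single controls. Without control replicate 2, 4 members were higher and 0 lower (median 0.30), and without control replicate 1, 0 were higher and 3 lower (median -0.16). Camera called neither shift (adjusted p = 0.0803 and 0.15 on the same genes). Mki67, a proliferation marker, was at 846 ± 451 and 891 ± 52.5, with control replicate 2 at 1367. Without that control it was called higher (log2 0.60, adjusted p = 0.00675).

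Interferon-stimulated genes fell together. Of 38 tested, 27 fell, 1 rose and 10 did not pass (30 and 1 when adjusted over the list alone), with a median log2 fold change of -0.61 (camera adjusted p = 2.36e-11; adjusted p = 0.489 with an estimated correlation). Rtp4 fell from 488 ± 121 to 131 ± 40.4, the guanylate-binding protein gene Gbp7 from 1548 ± 126 to 807 ± 35.0, and the antiviral synthetase gene Oas3 from 1071 ± 357 to 407 ± 70.6. The member that rose was Mx1 (268 ± 66.3 to 440 ± 58.1, adjusted p = 0.00853, chosen after its values were seen). Left-out replicates gave 15 to 28 members lower on the same genes.

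Genes of glycolysis and of ribosomal proteins were also lower. Of 18 glycolysis genes, 8 fell and 1 rose (10 and 1 when adjusted over the list alone; median -0.35, camera adjusted p = 0.000998; adjusted p = 0.469 with an estimated correlation). The glucose transporter gene Slc2a3 fell from 1200 ± 114 to 319 ± 48.7, Eno1 from 3719 ± 99.8 to 1890 ± 99.2 and Hif1a from 795 ± 19.8 to 543 ± 38.2, while the lactate transporter gene Slc16a3 rose (log2 0.95, chosen after its values were seen). Of 85 ribosomal protein genes, 38 fell and 0 rose in limma (47 and 0 when adjusted over the list alone), with a median of -0.41. The camera adjusted p was 1.56e-12, or 0.489 with an estimated correlation, and fry did not call the list (adjusted p = 0.0769). Rpl12 fell from 8894 ± 527 to 4004 ± 1030 and Rps16 from 5635 ± 341 to 3052 ± 537. With a GC and length correction 40 were lower and 1 higher, and without single libraries 19 to 60 were lower on the same genes, from 19 without control replicate 1 or cKOHet replicate 4 to 60 without cKOHet replicate 1. In the 4 libraries with high Xist alone, an alternative added after the data were seen, 8 were lower. Ribosomal protein genes took 8.26%, 7.23% and 7.67% of the signal in controls and 6.93%, 5.43% and 4.95% in cKOHet libraries. Of 13 mitochondrially encoded genes 0 were called in limma, with or without adjustment over the list alone (camera adjusted p = 0.106, median -0.25). The list was called lower without control replicate 4, cKOHet replicate 1 or cKOHet replicate 4 (adjusted p = 0.0173, 0.0252 and 0.0429), with library weights (0.0249) and in the libraries with high Xist alone (0.00507). Without cKOHet replicate 2, which had the smallest mitochondrial share of the signal, it was not (adjusted p = 0.978, median 0.06). With an estimated correlation (0.923 in this list) it had an adjusted p = 0.768, and no list was called in any of these alternatives. The member mt-Nd1 was at 6491 ± 714 and 4801 ± 1230 (adjusted p = 0.0692), and was called lower without cKOHet replicate 1 (0.0204), with robust eBayes (0.0495), with library weights (0.0272), with a replicate block (0.028) and with the GC and length correction (0.0381).

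**Figure D2:**
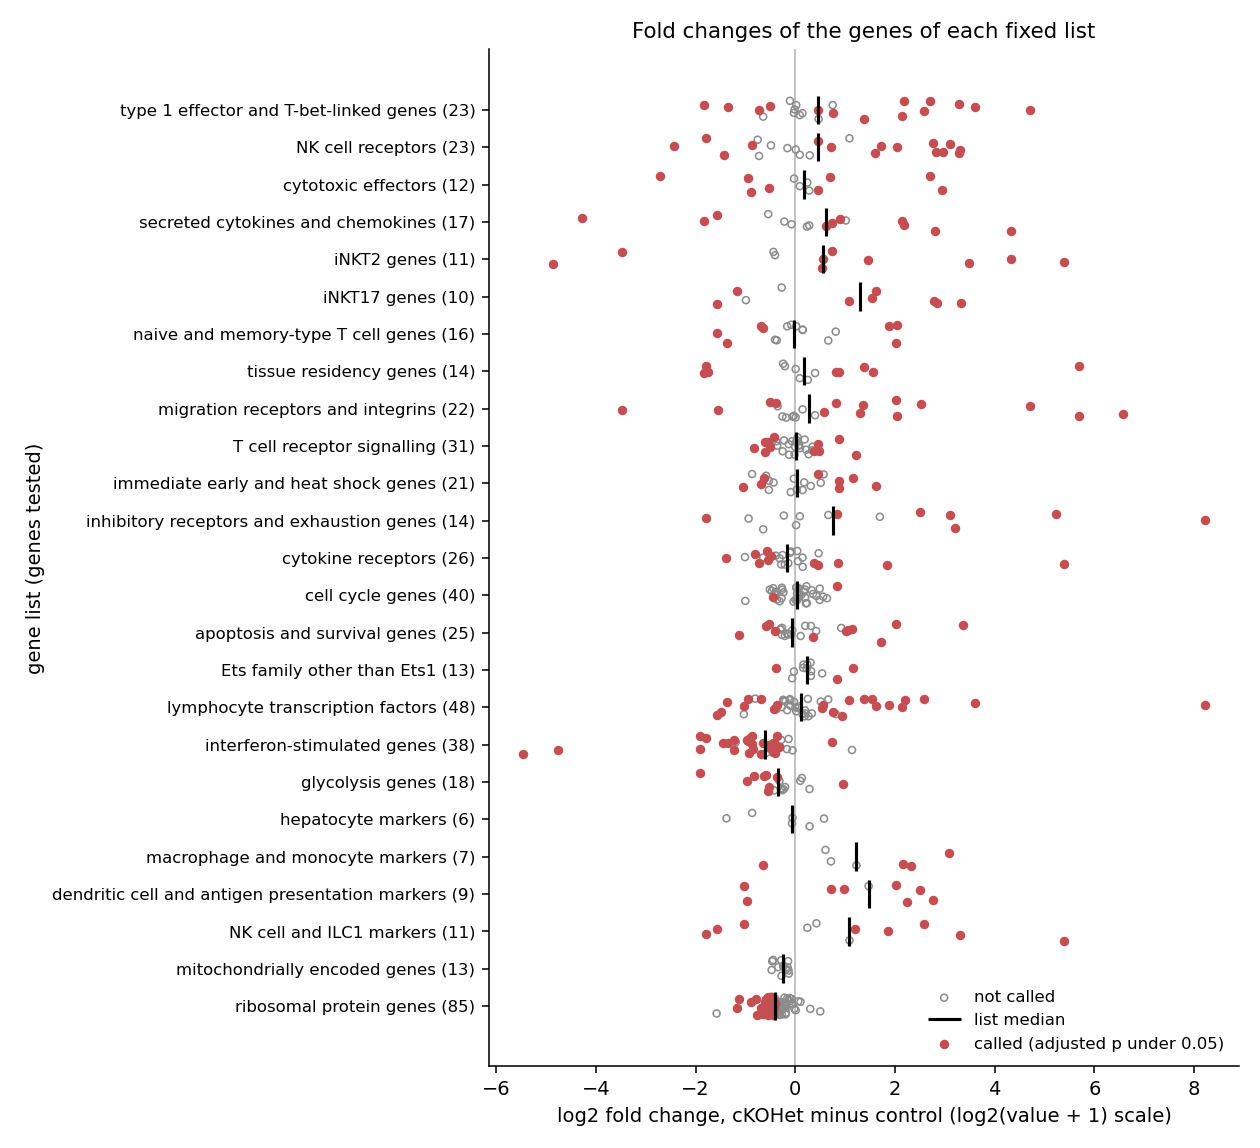
Log2 fold change (cKOHet minus control, on the log2(value + 1) scale) of each tested gene in the 25 lists with at least 5 tested members. Filled points are genes called at an adjusted p under 0.05, open points are not called, and black bars are list medians, which lie at -0.61 for interferon-stimulated genes and at -0.41 for ribosomal protein genes.

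Markers of other cells of the liver were mostly low. Of 6 hepatocyte markers 0 were called, with or without adjustment over the list alone (camera adjusted p = 0.811), and Alb, the most abundant, was at 227 ± 81.5 and 344 ± 156. Without cKOHet replicate 4 (75.8, against 6.06 and 3.56 in the other cKOHet libraries), Serpina3k was called lower (log2 -2.64, adjusted p = 0.00607). Of 7 macrophage and monocyte markers, Cd5l (2.26 ± 2.22 to 23.8 ± 11.4), Csf1r (6.15 ± 5.12 to 26.1 ± 1.67) and Clec4f (5.84 ± 4.95 to 26.6 ± 5.44) rose and Ctss (169 ± 27.1 to 107 ± 23.5) fell, with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.106, 0.0402 without control replicate 1 and 0.0488 with no filter; adjusted p = 0.489 with an estimated correlation, which called no list in these alternatives either). The call of Clec4f ended without cKOHet replicate 2 (adjusted p = 0.0602 on the same genes), its log2 fold change of 2.31 was 1.64 without control replicate 4, that of Cd5l was 2.43 rather than 3.09 without control replicate 2, and the call of Ctss ended without control replicate 1 or 2 or cKOHet replicate 1 or 4 (adjusted p = 0.0946, 0.168, 0.123 and 0.123), with library weights (0.0596) and with the GC and length correction (0.074). The call of Csf1r ended without cKOHet replicate 4 when the filter was applied again, but was kept on the same genes. Of 16 B cell markers only 2 were tested. Both fell, also over the list alone, Ighm from 1954 ± 94.9 to 943 ± 155 and Cd22 from 17.1 ± 4.67 to a listed 0.00 to 0.04. With no filter 4 B cell markers were tested, of which 1 was higher and 2 lower. Of the endothelial markers, Pecam1 fell from 196 ± 23.9 to 43.5 ± 7.48 and Stab1 rose from 5.51 ± 3.63 to 30.8 ± 14.8, both also over the list alone. The call of Stab1 ended without cKOHet replicate 4 (adjusted p = 0.0588 on the same genes). Mmp9 was the only neutrophil marker tested, and no erythroid marker passed the filter.

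Of 9 dendritic cell and antigen presentation markers, 6 rose and 2 fell (7 and 2 when adjusted over the list alone; camera adjusted p = 0.035; adjusted p = 0.489 with an estimated correlation). Itgax, the integrin chain CD11c, rose from 18.8 ± 4.37 to 134 ± 30.3, and the class II genes H2-Aa and H2-Eb1 from 6.54 ± 4.98 to 33.4 ± 6.98 and from 6.08 ± 4.24 to 29.3 ± 9.47 (the class II genes chosen after their values were seen). Bst2 and Irf8 fell by 0.98 and 1.04 on the log2 scale. The list call ended without cKOHet replicate 2 or 4 (adjusted p = 0.0574 and 0.053 on the same genes; with the filter applied again 0.0608 and 0.0429, so that the call was kept without cKOHet replicate 4), and also with no filter (0.0603), a filter of 50 (0.199) and the libraries with high Xist alone (0.0545). Of 11 NK cell and ILC1 markers, 5 rose and 3 fell (6 and 3 when adjusted over the list alone; camera adjusted p = 0.24). Klra8 rose from 3.06 ± 1.12 to 39.2 ± 10.3, and Tmem176a was among those that fell. The NK receptor gene Ncr1 (chosen after its values were seen) was at 5.52 to 9.47 in all 6 libraries, too low for the filter.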

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

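The corrections for GC content and length and for Xist, the libraries with high Xist alone, and the left-out replicates on the same genes were chosen after seeing the data. Calls numbered 2111 to 2548 under other pseudocounts, filters, scalings, variance models, the GC and length correction and a term for the Xist-low libraries, 1674 with the Xist-high libraries alone (fewer samples), 3030 at an adjusted p under 0.1, and 1173 when a 2-fold change was also required. Leaving out 1 replicate and filtering again gave 1779 to 2051 calls; on the genes of all 6 libraries, a version added after those values were seen, it gave 1883 to 2207. Genes called higher ranged from 857 to 1102 with filtering and from 1002 to 1174 on the same genes. The 857 was without cKOHet replicate 2 with the filter applied again, which drops genes present in cKOHet libraries alone (10917 tested). Lists called by camera numbered 8, with 4 to 10 when a replicate was left out (5 without cKOHet replicate 4 on the same genes), 4 with a filter of 50 and 0 with an estimated correlation. The interferon-stimulated, glycolysis and ribosomal protein lists kept their camera calls in all but the last. The last rests on few residual degrees of freedom and called no list in any setting, so it does not tell the lists apart. Fry on all 6 libraries called these 8 lists except the ribosomal protein genes (adjusted p = 0.0769). Camera did not call the cytotoxic, cytokine, iNKT2, iNKT17, apoptosis, Ets family, macrophage, or NK cell and ILC1 lists. Fry called each of them upward (adjusted p 0.00998 to 0.0406). Ets1 and Tbx21 kept their side of the threshold throughout (adjusted p of Tbx21 0.132 to 0.501). With the replicate block, 2412 genes were called, 2297 of them also without it, the NK cell receptor list lost its call (adjusted p = 0.0513) and mt-Nd1 gained one (adjusted p = 0.028). The deviations of same-numbered libraries from their group means correlated only weakly, at 0.092, 0.088 and 0.055, and the main fit did not pair them. In these deviations each library still correlated best with its own number, a hint from the data. Replicate 4 had almost no Xist in both groups, and the column codes of replicate 1 join 2 names in both. Whether libraries were matched by number is not stated in the labels and stays open. Of 122 named genes, 100 kept direction and side of the threshold in every alternative that tested them and 22 did not (2837 pairs of gene and alternative, 2714 the same; some low genes were filtered out of some alternatives). With the Xist-high libraries alone the calls of Mcm4, Nusap1, Elk4, Cd5l, Csf1r, Clec4f, Ctss, Irf8, Zbtb16 and Eomes ended (adjusted p 0.0605 for Elk4 to 0.236 for Nusap1) and Serpina3k was called lower (0.033). The 6 that reversed were not called with all 6 libraries: Klrb1c (-0.49 to 0.64 over left-out replicates, with -0.135 without control replicate 1 and -0.044 and -0.115 without cKOHet replicates 1 and 4; -0.002 with the GC and length correction), Tcf7 (-0.33 to 0.019, the latter without cKOHet replicate 2), Il7r (-0.094 to 0.39, with -0.021 without cKOHet replicate 4), Cxcr6 (-0.073 to 0.10, with -0.009 without control replicate 2 and -0.005 and -0.064 without cKOHet replicates 1 and 4; -0.058 with library weights, -0.14 with Xist-high libraries), Mki67 (-0.016 to 0.60, with 0.00 without control replicate 1; -0.064 with Xist-high libraries) and Alb (-0.077 with Xist-high libraries). Of these, Klrb1c was called higher without control replicate 4 and Mki67 without control replicate 2 (limma adjusted p = 0.0486 and 0.00675 on the same genes). The cause was not tested. The planned edgeR and DESeq2 tests on recovered reads were not run, because the values are not whole multiples of one step. Original depth is unknown, so no limit from counts could be set for low genes.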

Other observations

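The symbol families, the Cd8b1 share, the T cell receptor medians, the odds near the targeted genes, the GC and length correction, the equal numbers of Xist-high libraries and the Xist-based refits were tests chosen after the results were seen. The alpha-chain V share, the Xist interval and the splits were set before. All genes in the first 2 paragraphs, and Cd8b1, Ncr1, Tyrobp and Fcer1g, were chosen after their values were seen.

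Genes of S100 calcium-binding proteins rose together. All 6 tested S100a genes were called higher (adjusted p = 0.000462, Fisher's exact test, one-sided, over 612 family and direction tests). The 6 calls held with TMM, quantile and GC and length scaling. Families were formed from the letters that open a symbol, a rule that would have dropped S100a. This family was added by hand, so its adjusted p is not that of a family found by the rule. S100a4 rose from 232 ± 61.4 to 2958 ± 606 (n = 3 per group), S100a6 from 511 ± 109 to 3130 ± 428 and S100a11 from 783 ± 80.3 to 2297 ± 61.1. Of 7 annexin genes 5 were higher (adjusted p = 0.0279), with Anxa2 going from 562 ± 78.6 to 2551 ± 204. The galectin genes Lgals1 (1045 ± 92.1 to 7888 ± 681) and Lgals3 (74.8 ± 10.4 to 2470 ± 143) rose as well, although 3 of 6 galectins was not an enrichment (adjusted p = 0.704). Among Krüppel-like factors 6 of 10 were higher (adjusted p = 0.0279), including Klf9 (4.33 to 29.7 in controls, 81.7 to 95.6 in cKOHet libraries). The p200 and related Ifi genes were lower at 9 of 11 (adjusted p = 3.11e-05), including Ifi206 (1470 ± 164 to 588 ± 17.2). Counting every biotype, 9 of 12 were lower and 1, Ifi27, higher (means of 519 and 755, adjusted p = 0.0415), with 8 lower and 0 higher in limma after quantile scaling and 8 lower and 1 higher with the GC and length correction. Members of such families can share reads.

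Transcripts of the T cell receptor beta locus were lower while those of the alpha locus were not. Trbc1 fell from 3452 ± 275 to 2031 ± 327 (log2 -0.77, SE 0.13, adjusted p = 0.000482) and Trbc2 from 5038 ± 524 to 2195 ± 273 (log2 -1.20, adjusted p = 6.78e-06). Trac was at 3592 ± 700 and 3852 ± 169 (log2 0.12, adjusted p = 0.618), and Cd3d, Cd3e and Cd3g were not called. Of 12 Trbv segments 8 were lower (adjusted p = 0.000462), or 4 with the GC and length correction. The share of Trbv signal outside the segments Trbv1, Trbv13 and Trbv29, which iNKT receptors favour, was 13.8 ± 1.75% in controls and 12.1 ± 0.10% in cKOHet libraries.

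The higher Cd8a with lower Cd4 could come from conventional CD8 T cells that passed the sort. Such cells carry Cd8b1 at a level similar to Cd8a, yet the excess of Cd8b1 over controls was 0.53% of the excess of Cd8a, which argues against them. The share of alpha-chain V signal outside Trav11 and Trav11d was 77.81 ± 8.95% in controls and 82.65 ± 4.07% in cKOHet libraries. The difference of 4.84 percentage points was within the spread and drawn from little signal (90.2 to 175.5 per library). Most of this signal lay outside these segments even in the tetramer-sorted controls, so the share adds nothing either way. Cells with CD8 made of 2 alpha chains, or iNKT cells that gained Cd8a, remain open. Gamma delta T cells were not tested.

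The NK receptor and cytotoxic genes could come from NK cells or other innate lymphocytes without a T cell receptor mixed into the cKOHet libraries, although the sort for the CD1d tetramer should remove most of them; its purity is not given in the sources used here. The median log2 fold change of Cd3d, Cd3e, Cd3g, Trac, Trbc1 and Trbc2 was 0.09, but these members went both ways (0.34 for Cd3e and Cd3g, -0.77 and -1.20 for Trbc1 and Trbc2), so it decides nothing. Ncr1, a gene that NK cells express strongly, was at 5.52 to 9.47 in all libraries, and Prf1 fell from 438 ± 109 to 69.8 ± 36.6. Tyrobp, an adaptor of NK and myeloid cells, was called higher (adjusted p = 0.0462), but with cKOHet replicate 4 inside the control range (98.7, 92.9 and 34.4, against 22.9, 28.6 and 38.1), and Fcer1g, another such adaptor, was not called (50.6 ± 11.6 and 67.9 ± 14.6). No test here decides, so such cells stay open as a source, beside a change within the sorted iNKT cells and a change in subset composition, neither of which was tested.

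Of the 10 splits of the libraries, 1, the real one, gave as many as 2407 calls, and the highest other gave 1; 10 splits are too few for a share under 0.05. A passenger segment around a floxed allele could add calls near Ets1 or Tbx21: 66 of 275 genes within 10 Mb were called, an odds ratio of 1.16 (95% interval 0.86 to 1.54; Fisher's exact test, two-sided, p = 0.299), which leaves some excess open, although these genes hold only 2.74% of the calls. Sex differed within groups and not between them: replicate 4 of each group had almost no Xist (1.17 and 0.08, against 4337 to 5657 in the others) and a sum of 4 Y-linked genes of 1501 and 1550. The Xist log2 fold change was -0.22 with an interval of -6.34 to 5.90, too wide for the bound set before, so the argument against sex rests on the equal numbers, a criterion chosen after Xist was seen. The 4 libraries with high Xist alone gave 1674 calls, 1573 of them among the 2407.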
